A study of Arabidopsis thaliana with 12 samples.

How the data were processed

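RNA from young leaves of Arabidopsis thaliana, accession Columbia, was measured on 12 Affymetrix ATH1 arrays. Plants grew in peat pellets at 22 degrees C with 10 h of light per day. In the moderate drought, water was withheld from 30 days after sowing and the soil was then held at 30% of field capacity; leaves were taken on day 1 and on day 10. In the progressive drought, water was withheld from 35 days after sowing and leaves were taken on the first day of wilting. Each of the 3 samplings had its own well-watered control, which gives 6 groups of 2 arrays. Every array carried RNA from a pool of 5 plants, so n counts pools, and the small number of arrays limits the precision of every value. Per the labels' protocols, RNA was purified on RNeasy columns with DNase and labelled with biotin through in vitro transcription from the 3' end.

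The deposited values are log2 expression values made by the authors with RMA, which subtracts background, quantile-normalises the arrays and summarises the probes of each set by median polish. The submitters' processing notes name RMA and the affy package, and their versions are not given in the sources used here. Probe sets carry locus codes, so the probes had been regrouped by locus, with 1 probe set per locus. The build of that regrouping is not given in the sources used here. Sorted values differed on average by 0.0501, 0.0586 and 0.0691 log2 units within the 4 arrays of day 1, day 10 and progressive drought, against 0.696 over all 12 arrays. The 3 comparisons had therefore been normalised as separate sets of 4 arrays, and expression levels were not compared across sets. Median log2 values per array lay between 4.65 and 5.63. The 56 control probe sets were left out of the tests, which leaves 21461 probe sets, 72 of them antisense. Names came from a RefSeq table of locus tags without coordinates: 21164 of the 21389 sense loci were found there and 8982 had a symbol. Genes without a symbol were counted but not named.

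Drought minus control was estimated per comparison with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust) on the deposited log2 values, with a mean for each of the 6 groups. All 12 arrays gave 1 estimate of the spread per probe set, with 6 residual and 2.78 prior degrees of freedom. Tests were two-sided and Benjamini-Hochberg adjusted over the 21461 probe sets of each contrast, and a probe set was called at an adjusted p under 0.05. Differences between the 3 drought effects were tested as interaction contrasts in the same fit. Errors after the ± sign are standard errors of this fit unless another fit is named. Replicate numbers did not pair drought with control arrays: the replicate differences of the 2 arms correlated across probe sets at 0.03, 0.06 and −0.49 for day 1, day 10 and progressive drought, so no replicate block was used.

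Lists of genes by pathway, family and cell type, 38 in all, were fixed before the data were examined. They held 740 entries, of which 691 were measured and 2 were left out because the name and the locus did not match. Each list needed at least 4 measured members. Shifts were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 114 list and comparison pairs, and the differences between effects formed another family. No list shift held with a correlation estimated from the residuals, and fry, limma's rotation test of whether the genes of a list move on balance 1 way, called 21 of the 114, 16 of them among the 38 shifts that camera called. The lists overlap in part. The planned list of cytosolic ribosomal proteins was not tested because the table used has no descriptions. Named genes were chosen by a rule: the drought sentinel genes, the 10 largest called rises and the 10 largest called falls with a symbol and with drought and control arrays that did not overlap, and up to 4 called members of each list that shifted, those with the smallest adjusted p first. For each difference between effects the 5 largest in each direction were taken. After the data were seen, the 10 largest were also taken from the fits of 4 arrays alone, which added the day 1 genes of that fit and 1 of the 80 called progressive genes. Of the 8 sentinel genes 7 were measured. Every called probe set in the 3 comparisons had arrays that did not overlap. With 2 arrays per group a call on the same arrays all but fixes this, so it adds no support. Chance gives it for 33.3% of probe sets that were not selected by a test. A clock index per array was the mean log2 value of 8 dawn-phased genes minus that of 8 dusk-phased genes, the measured ones of 9 and 10 listed. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

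The test was tested on simulated data, with 200 of 21461 probe sets changed in each of 10 simulations. When all groups had equal spread, 77.9% to 81.0% of changes of 1 log2 unit and 97.6% to 98.7% of changes of 2 log2 units were recovered, and 4.66% to 5.19% of the calls were false. For the measured spreads, every probe set's SD was scaled by its group's root mean square SD. False calls per simulation were then 0.2 on day 1, 3.0 on day 10 and 304.2 in progressive drought, 61.4% of the calls there. Array weights brought that share to 5.30% and recovered 91.0% of changes of 2 log2 units in progressive drought, but 44.2% of changes of 1 log2 unit, where the fit without weights recovered 85.7%. Across groups the median SD (0.07 to 0.14) differed less than the root mean square SD (0.12 to 0.37). The progressive false calls may therefore be too many for a typical probe set. The shares of false calls also depend on how many probe sets were changed, so they do not carry over to the measured counts. Noise was drawn independently for each probe set, so these shares do not cover correlated genes. Alternatives tried were an intensity trend, a robust prior, array weights, replicate blocks, median centring, cyclic loess, quantile normalisation over all arrays, a filter on dim probe sets, stricter thresholds, a fit on the 4 arrays of a comparison alone, and leaving out each array in turn.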

Results

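Expression was measured in young leaves on 12 arrays in 6 groups of 2: control and moderate drought on day 1, control and moderate drought on day 10, and control and progressive drought on the first day of wilting. Replicate arrays correlated across probe sets at 0.997 and 0.995 on day 1, 0.994 and 0.989 on day 10, and 0.974 and 0.964 in the progressive comparison, control first. The root mean square SD between replicates was 0.12 and 0.15 log2 units on day 1, 0.15 and 0.21 on day 10, and 0.31 and 0.37 in the progressive comparison. Changes below are log2 differences, drought minus control, with their SE where given and n = 2 arrays per group, and fold changes are on the linear scale. List members given without a call, or called outside the naming rule, are examples chosen after their values were seen.

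The first comparison asks which leaf transcripts differ on day 1 of moderate drought, at the onset of a response that the study follows towards acclimation of growth. LTP4 (AT5G59310), a lipid transfer protein, rose by 4.51 ± 0.36. CPUORF47 (AT5G03190), named for a conserved upstream open reading frame, rose by 1.95 ± 0.12, and YSL2 (AT5G24380), a transporter of metal chelates, rose by 1.20 ± 0.12. CSD2 (AT2G28190), the chloroplast copper/zinc superoxide dismutase, fell by 3.41 ± 0.32, or 10.6-fold. These 4 were the only probe sets called with all 12 arrays, at adjusted p of 0.0067, 0.0013, 0.0309 and 0.0179 in that order. In all, 1865 had an unadjusted p under 0.05 against 1073 for chance alone. The same comparison gave 187 calls with the 4 arrays of day 1 alone and 165 with array weights, and the day 1 arrays varied less between replicates than those of progressive drought.

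In the fit of the 4 day 1 arrays alone, 108 probe sets rose and 79 fell. The largest rises there were those of LTP3 (4.54 ± 0.22), a close relative of LTP4, LTP4 itself (4.51 ± 0.15), LEA7 (4.31 ± 0.55) and the dehydrin RAB18 (3.27 ± 0.31), both protective proteins of drying tissue. PELPK1 (2.91 ± 0.11), a cell wall protein, and FER1 (2.70 ± 0.15), which stores iron, followed. Next to CSD2, the largest falls were CCS (−2.07 ± 0.10), which loads copper into superoxide dismutases, and CSD1 (−2.06 ± 0.16), the cytosolic copper/zinc superoxide dismutase. Control means of LTP4, LTP3, LEA7 and PELPK1 lay below the median of those arrays, 5.62, as the drought mean of bHLH39 did below 5.61. Whether such levels exceed background was not tested, so the sizes and order of these changes are approximate. The iron-deficiency factor bHLH39 (−1.66 ± 0.22), the abscisic acid (ABA) receptor PYL4 (−1.62 ± 0.11) and the calcium-binding TCH3 (−1.35 ± 0.10) fell as well. Adjusted p in that fit was 0.0018 for LTP3, 7.3e-04 for LTP4, 0.0365 for LEA7, 0.0219 for RAB18, 0.0018 for CCS, 0.0116 for CSD1 and 0.0066 for PYL4. Of these only LTP4 passed with all 12 arrays, where RAB18 was at an adjusted p of 0.083 and the ABA-responsive LTI65 (RD29B) at 1.92 ± 0.39 and 0.194.

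Genes that respond to ABA and dehydration rose as a group on day 1, with 20 of 21 members above 0 and a median of 0.57 (adjusted p = 1.2e-07; adjusted p = 0.375 with an estimated correlation). No member was called over all genes, and 4 rose adjusted over the list alone, among them RAB18 (3.27), LTI65 (1.92) and the homeobox gene HB-7 (1.77). LTI30 (1.84) was not among the 4, and RD26 was at 1.15 and RD22 at 0.56. The clade A PP2C phosphatases, which hold ABA signalling in check, rose with a median of 0.71 and 9 of 9 members above 0 (adjusted p = 1.6e-05; adjusted p = 0.346 with an estimated correlation). HAI2 (1.68), HAI1 (1.10), PP2CA (0.96) and ABI2 (0.81) rose adjusted over the list alone, and 0 were called over all genes by limma. The PYR/PYL receptors, which bind ABA, fell with a median of −0.30 and 6 of 10 members below 0 (adjusted p = 0.00632; adjusted p = 0.297 with an estimated correlation). PYL4 and PYL5 were the 2 members that fell adjusted over the list alone. Transcription factors tied to drought and ABA rose with 25 of 31 members above 0 and a median of 0.32 (adjusted p = 8.1e-04; adjusted p = 0.297 with an estimated correlation). HB-7 was the 1 factor called adjusted over the list alone, while NAP was at 1.33, NAC019 at 1.17 and ABF3 at 0.79. Late embryogenesis abundant proteins and dehydrins rose with 27 of 31 members above 0 and a median of 0.29 (adjusted p = 9.7e-04; adjusted p = 0.480 with an estimated correlation), and 2 rose adjusted over the list alone. The sentinel drought genes rose as a list of 7 with a median of 0.69 (adjusted p = 0.0142; adjusted p = 0.375 with an estimated correlation). Adjusted over the list alone, 2 sentinel genes rose and 1 fell. Among those not yet given, LTI78 (RD29A) was at 0.69 ± 0.68, NCED3, which makes the rate-limiting step to ABA, at 0.59 ± 0.30, and ERD5, which breaks down proline, at −1.55 ± 0.42.

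Cell division genes fell on day 1 by a small margin, with 24 of 26 members below 0 and a median of −0.17 (adjusted p = 8.8e-05; adjusted p = 0.375 with an estimated correlation). The kinesin HIK was at −0.57 and the mitotic cyclin CYCB1;1 at −0.39, and 0 members were called by limma, over all genes or adjusted over the list alone. Chlorophyll synthesis genes fell with 13 of 16 below 0 and a median of −0.18 (adjusted p = 0.00207; adjusted p = 0.483 with an estimated correlation). Of these, 2 fell adjusted over the list alone, and the magnesium chelatase genes CHLI1 and CHLI2 were at −0.61 and −0.59. Markers of 2 other tissues moved on the same day. Vascular markers rose with a median of 0.32 and 9 of 11 members above 0 (adjusted p = 8.8e-04; adjusted p = 0.483 with an estimated correlation). XCP2 (0.90), IRX12 (0.60), IRX3 (0.54) and XCP1 (0.53) rose adjusted over the list alone. Shoot apex and floral markers rose with a median of 0.13 and 14 of 17 members above 0 (adjusted p = 0.0381; adjusted p = 0.375 with an estimated correlation), with AP1 at 0.39. The other 28 lists did not pass on day 1, at adjusted p from 0.0844 to 0.992.

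CPUORF47 kept its call whichever array was left out, while the number of calls became 1 without either control array of day 1, 2 without drought replicate 1 or either control array of day 10, 8 without drought replicate 2, 16 without either progressive control array and 31 without either progressive drought array. Without drought replicate 1 of day 1 the adjusted p became 0.064 for the sentinel genes, 0.068 for the receptors and 0.0603 for the transcription factors, and without control replicate 1 it became 0.0524 for chlorophyll synthesis and 0.107 for the shoot apex markers. The shoot apex markers were also lost with cyclic loess (adjusted p = 0.0631), array weights (0.0506) and the 4 arrays alone (0.0995). Across the 12 fits without an array the median ran from 0.35 to 1.09 for the sentinel genes, from −0.41 to −0.20 for the receptors and from 0.07 to 0.17 for the shoot apex. The rotation test fry passed 0 of the 10 lists, at adjusted p from 0.0603 to 0.210. With the filter on dim probe sets the camera adjusted p became 0.221 for cell division, 0.122 for vascular markers and 0.806 for the shoot apex.

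**Figure D1:**
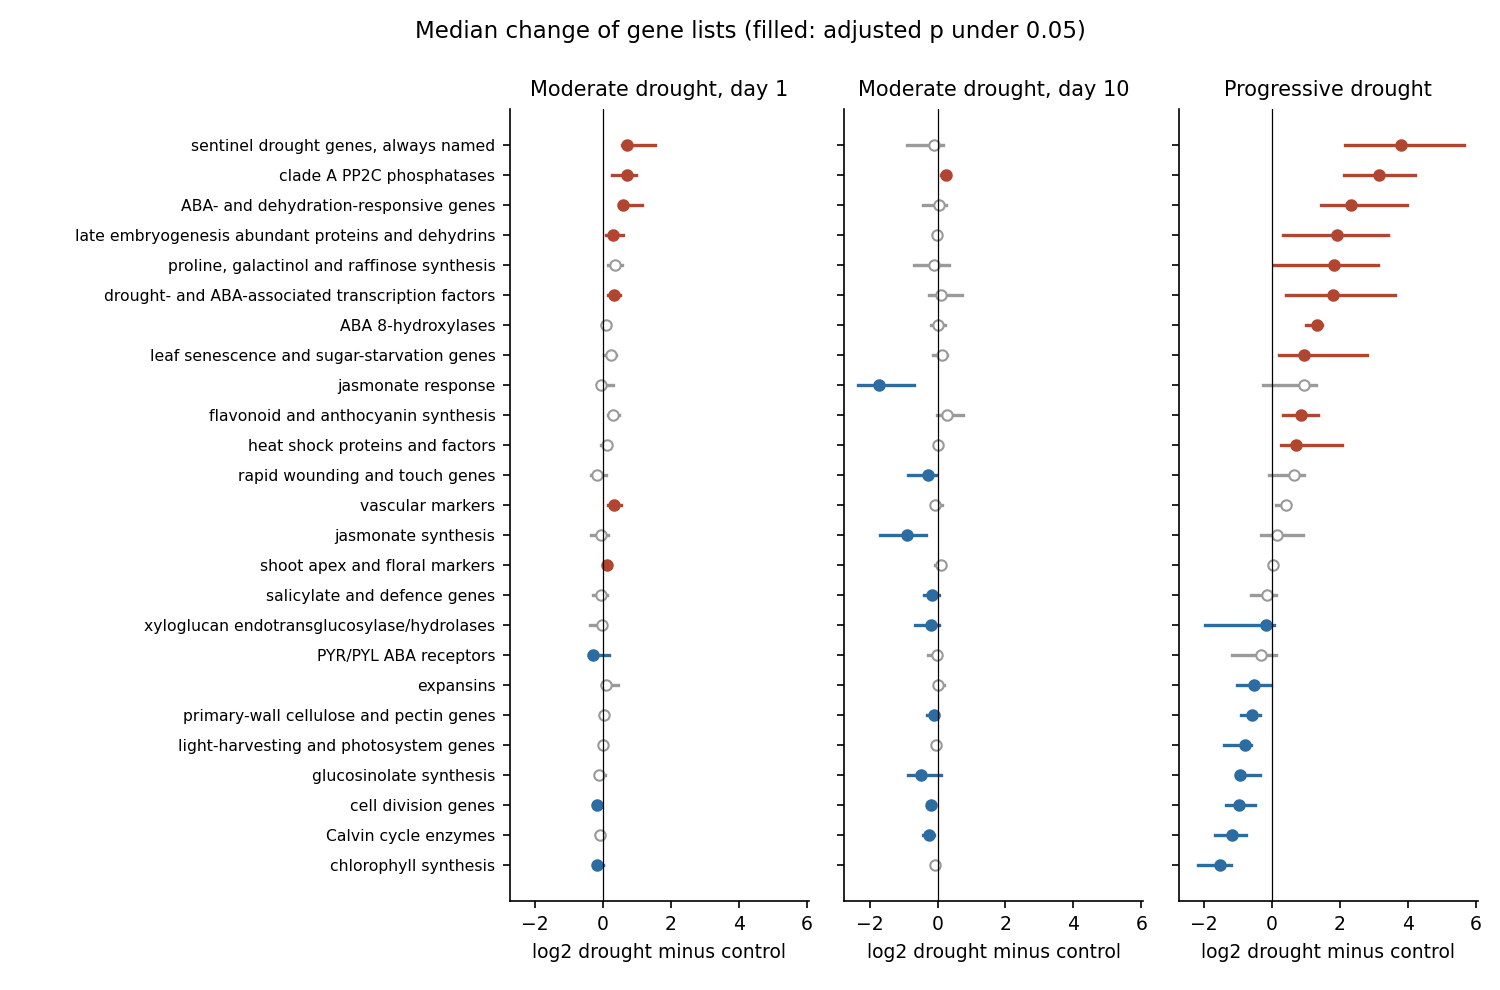
Median log2 change of each gene list that passed in at least 1 comparison, drought minus control, with bars from the lower to the upper quartile of its members and filled points where camera gave an adjusted p under 0.05. The ABA and dehydration list stood at 0.57 on day 1 and 2.33 in progressive drought, and the jasmonate response list at −1.72 on day 10.

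The second comparison asks what differs after 10 days at the same moderate drought, once plants had been held at constant soil moisture. HIS1-3 (AT2G18050), a linker histone, rose by 2.29 ± 0.21, GLN1;4 (AT5G16570), a cytosolic glutamine synthetase, by 1.67 ± 0.15, and the beta-glucosidase BGLU11 (AT1G02850) by 1.32 ± 0.12. The homeodomain gene BEL1 (1.31 ± 0.18), the bZIP factor TGA7 (1.27 ± 0.16), ALN (1.26 ± 0.17), which degrades allantoin, and RPK1 (1.04 ± 0.14), a receptor kinase of ABA signalling, also rose. NIA2 (AT1G37130), a nitrate reductase, fell by 1.91 ± 0.20 and CLC-A (AT5G40890), which moves nitrate into the vacuole, fell by 1.43 ± 0.19. The fasciclin-like arabinogalactan proteins FLA13 (AT5G44130; −1.98 ± 0.17), FLA9 (−1.41 ± 0.16) and FLA2 (−1.13 ± 0.13) fell, as did the wall-loosening enzyme XTH16 (−1.45 ± 0.14) and SHV3 (−1.18 ± 0.15), which is needed for cellulose deposition. MSRB6 (−1.89 ± 0.24), a methionine sulfoxide reductase, KCS1 (−1.05 ± 0.13), which elongates fatty acids for wax, and SBH2 (−1.01 ± 0.12), a sphingoid base hydroxylase, fell too. In all, 10 probe sets rose and 13 fell, with adjusted p of 0.0082 for FLA13 and HIS1-3, 0.0172 for NIA2, 0.0476 for CLC-A and 0.0498 for RPK1, and 2238 had an unadjusted p under 0.05.

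Jasmonate genes formed the largest group shift on day 10. Jasmonate response genes fell with a median of −1.72 and 17 of 18 members below 0 (adjusted p = 1.6e-05; adjusted p = 0.54 with an estimated correlation). The repressors JAZ7 (−3.92 ± 1.80) and JAZ10 (−3.09 ± 1.40), the tyrosine aminotransferase TAT3 (−2.89 ± 1.04) and the master regulator MYC2 (−1.52 ± 1.25) had wide errors. The receptor gene COI1 was at 0.60, and 0 members were called by limma, over all genes or adjusted over the list alone. Jasmonate synthesis genes fell with 11 of 12 below 0 and a median of −0.91 (adjusted p = 9.4e-04; adjusted p = 0.589 with an estimated correlation). The lipoxygenase LOX4 was at −3.12 ± 1.44, LOX3 at −2.79 ± 1.55 and AOC3 at −1.65 ± 0.68, and 0 were called by either adjustment. Rapid wounding and touch genes fell with 14 of 19 below 0 and a median of −0.28 (adjusted p = 0.0232; adjusted p = 0.784 with an estimated correlation), and 3 fell adjusted over the list alone. Salicylate and defence genes fell with 14 of 22 below 0 and a median of −0.16 (adjusted p = 0.0337; adjusted p = 0.707 with an estimated correlation). The pathogenesis-related genes BGL2 (PR2) and PR5 were at −1.95 ± 0.50 and −1.86 ± 0.27, and 1 member rose and 3 fell adjusted over the list alone. Glucosinolate synthesis genes fell with 13 of 21 below 0 and a median of −0.48 (adjusted p = 0.0413; adjusted p = 0.821 with an estimated correlation), with the regulator MYB34 at −2.01 and 0 called by either adjustment.

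Lists of wall, division and carbon-fixation genes also fell on day 10. The xyloglucan endotransglucosylase/hydrolases (XTHs), which cut and rejoin wall polymers, fell with 16 of 26 below 0, a median of −0.19 and a mean of −0.46 (adjusted p = 2.0e-04; adjusted p = 0.297 with an estimated correlation). XTH16 fell over all genes, 4 fell adjusted over the list alone, and TCH4 was at −2.99 ± 0.56 and XTH4 at −1.02. Cell division genes fell with 20 of 26 below 0 and a median of −0.18 (adjusted p = 8.1e-04; adjusted p = 0.480 with an estimated correlation), and PCNA1, the clamp of DNA replication, at −0.68 ± 0.11, was the 1 member that fell adjusted over the list alone. Calvin cycle enzymes fell with 15 of 17 below 0 and a median of −0.25 (adjusted p = 0.00182; adjusted p = 0.540 with an estimated correlation). Genes for cellulose and pectin of the primary wall fell with 11 of 14 below 0 and a median of −0.10 (adjusted p = 0.0337; adjusted p = 0.540 with an estimated correlation), and limma called 0 members of either of these lists by either adjustment. The PP2C phosphatases were the 1 list that rose, with 7 of 9 above 0 and a median of 0.26 (adjusted p = 0.0381; adjusted p = 0.637 with an estimated correlation), and HAI2, at 1.70 ± 0.26, rose adjusted over the list alone. The sentinel genes did not pass on day 10 (adjusted p = 0.259): LTI78 was at 0.25 ± 0.68, LTI65 at 0.10 ± 0.39, RAB18 at −0.10 ± 0.48, NCED3 at 0.33 ± 0.30, COR15A at −0.78 ± 0.62, RD20 at −0.99 ± 0.60 and ERD5 at −1.34 ± 0.42. The senescence regulators NAP (2.39 ± 0.61) and NAC6 (ORE1; 2.34 ± 0.39) were not called over all genes. The 28 lists that did not pass on day 10 had adjusted p from 0.0591 to 0.967, and markers of other tissues were among them.

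In the fit of the 4 day 10 arrays alone limma called 0 probe sets, with 3038 at an unadjusted p under 0.05, and with array weights it called 158. Array weights gave 97 rises and 61 falls, and cyclic loess 4 rises and 11 falls. Without control replicate 1, control replicate 2 or drought replicate 1 of day 10 the count was 0, without 1 of the day 1 arrays 7 or 8, without drought replicate 2 of day 10 36, and without 1 of the progressive arrays 88 or 92. Without drought replicate 2 of day 10 the adjusted p became 0.141 for phosphatases, 0.216 for cellulose and pectin, 0.220 for wounding, 0.438 for glucosinolates and 0.542 for defence, and without drought replicate 1 it became 0.305 for the Calvin cycle. With cyclic loess it became 0.0914 for cellulose and pectin, 0.0614 for defence and 0.126 for glucosinolates. Across the 12 fits without an array the median ran from −0.36 to −0.11 for the Calvin cycle, from −0.30 to −0.02 for defence, from −0.23 to −0.05 for cellulose and pectin and from −0.52 to −0.15 for wounding. It ran from −0.65 to −0.32 for glucosinolates, from −0.28 to −0.15 for the XTHs, from −0.19 to −0.12 for cell division and from 0.12 to 0.26 for phosphatases. The rotation test fry passed 1 of the 10 lists, the XTHs (adjusted p = 0.0436), and put jasmonate response at 0.392.

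**Figure D2:**
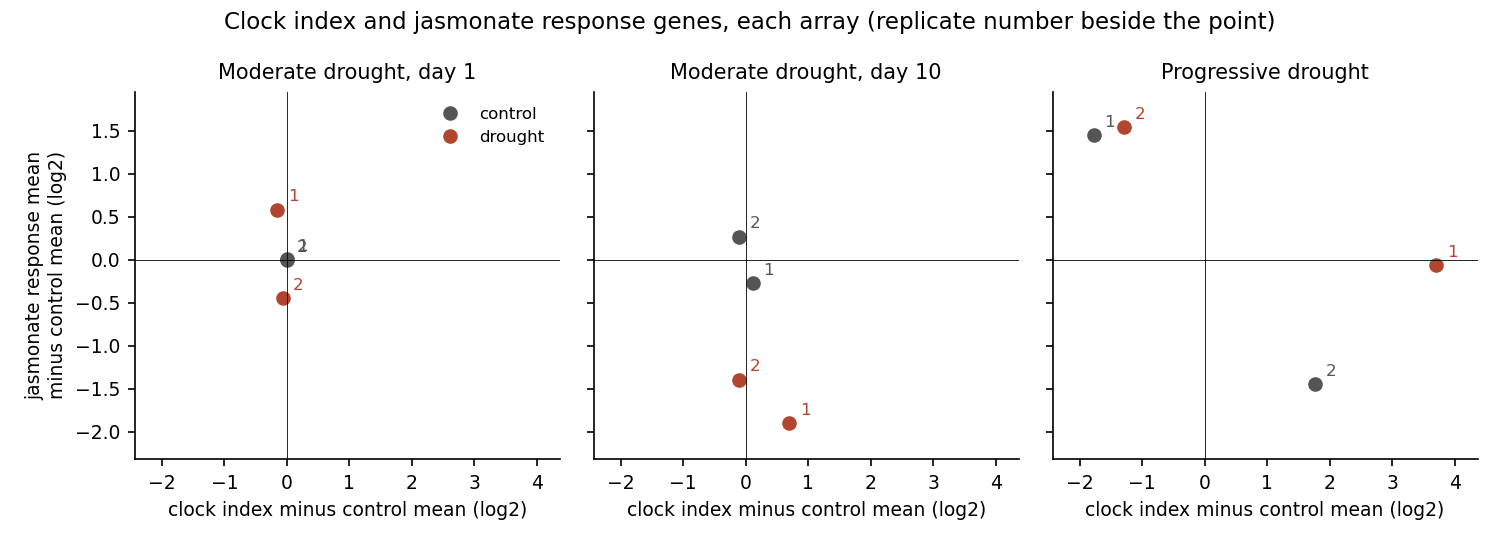
Mean log2 of the jasmonate response genes on each of the 12 arrays against a clock index, the mean log2 of dawn-phased minus that of dusk-phased clock genes, both relative to the control mean of the same comparison. The day 10 drought arrays lie at −1.90 and −1.40 on the jasmonate axis, and the 2 progressive drought arrays lie 5.00 apart on the clock axis.

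The third comparison asks which transcripts differ when soil water was left to run out until leaves wilted, as a contrast to the steady moderate drought. LEA7 (AT1G52690) rose by 9.45 ± 0.60, RAB18 (AT5G66400) rose by 8.37 ± 0.48, and LTP4 rose by 8.05 ± 0.36. LEA4-5, another protective protein (7.52 ± 0.25), LTI65 (7.41 ± 0.39), LTP3 (6.93 ± 0.60), TSPO (6.74 ± 0.41), a membrane protein induced by ABA, HAI2 (6.56 ± 0.26), HAI1 (6.41 ± 0.36) and the homeobox gene HB-12 (6.19 ± 0.31) were the other named rises. Control means of 8 of these 10, all but RAB18 and LTP3, lay below the median of the control arrays, 4.69. RAB18 was the highest value on drought replicate 1. The sizes and order of these rises are therefore approximate. The largest named fall was that of CSD2 (−5.47 ± 0.32), followed by the germin-like genes GER1 (−5.12) and GER3 (−4.34), XTH6 (−4.64), XTH9 (−4.05), the gibberellin-induced GASA6 (−4.61) and the growth-promoting factor HBI1 (−4.22). EXO (−3.90), which promotes leaf growth, EXL5 (−3.78) and FLA2 (−3.77) fell as well, and the drought means of XTH6, HBI1, EXO and FLA2 lay below the array median of 4.67. With all 12 arrays 2692 probe sets rose and 3105 fell, with 7730 at an unadjusted p under 0.05, and 1177 of the rises and 1497 of the falls had a log2 change of at least 1. Array weights, which allow for the wider spread of these arrays, called 1963 rises and 2312 falls, the 4 arrays alone 589 and 986, and cyclic loess 2996 and 2835.

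Several lists of ABA-related genes rose in progressive drought. The PP2C phosphatases rose with a median of 3.15 and 8 of 9 members called, over all genes and adjusted over the list alone (adjusted p = 3.8e-09; adjusted p = 0.283 with an estimated correlation). ABI2 (4.23) and ABI1 (3.15) were among them. ABA- and dehydration-responsive genes rose with a median of 2.33, with 16 of 21 called over all genes and 18 adjusted over the list alone (adjusted p = 1.1e-10; adjusted p = 0.297 with an estimated correlation). Late embryogenesis abundant proteins and dehydrins rose with a median of 1.90, with 21 of 31 called and 24 adjusted over the list alone (adjusted p = 6.3e-11; adjusted p = 0.269 with an estimated correlation). Among transcription factors tied to drought and ABA 20 of 31 rose and 1 fell, HB5 (−1.30), with 21 and 1 adjusted over the list alone and a median of 1.79 (adjusted p = 3.8e-09; adjusted p = 0.211 with an estimated correlation). HB-7 (5.74), NAC032 (4.64) and ABF3 (3.43) were among the risers. The ABA 8'-hydroxylases, which degrade ABA, rose with 3 of 4 called by either adjustment and a median of 1.33 (adjusted p = 0.00361; adjusted p = 0.375 with an estimated correlation). These were CYP707A1 (1.65), CYP707A2 (1.42) and CYP707A3 (1.24). The sentinel genes had a median of 3.81, with 5 of 7 rising and 1 falling over all genes, and 6 and 1 adjusted over the list alone (adjusted p = 9.7e-04; adjusted p = 0.297 with an estimated correlation). NCED3 rose by 3.81 ± 0.30, RD20, a calcium-binding protein of lipid droplets, by 3.90 ± 0.60 and LTI78 by 2.66 ± 0.68. ERD5 fell by 1.93 ± 0.42, and COR15A was at 1.67 ± 0.62 and not called over all genes. ABA synthesis as a list did not pass with camera (adjusted p = 0.264; up with fry, 0.00853), with 3 members up, NCED3, AAO3 (2.76) and ABA3 (0.91), and 2 down, NPQ1 (−1.17) and ABA2 (−0.88). The PYR/PYL receptors did not pass with camera either (adjusted p = 0.0902; down with fry, 0.00409), with 4 members down, PYL4 (−2.35), RCAR3 (−1.34), PYL5 (−1.28) and PYL1 (−0.89).

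**Figure D3:**
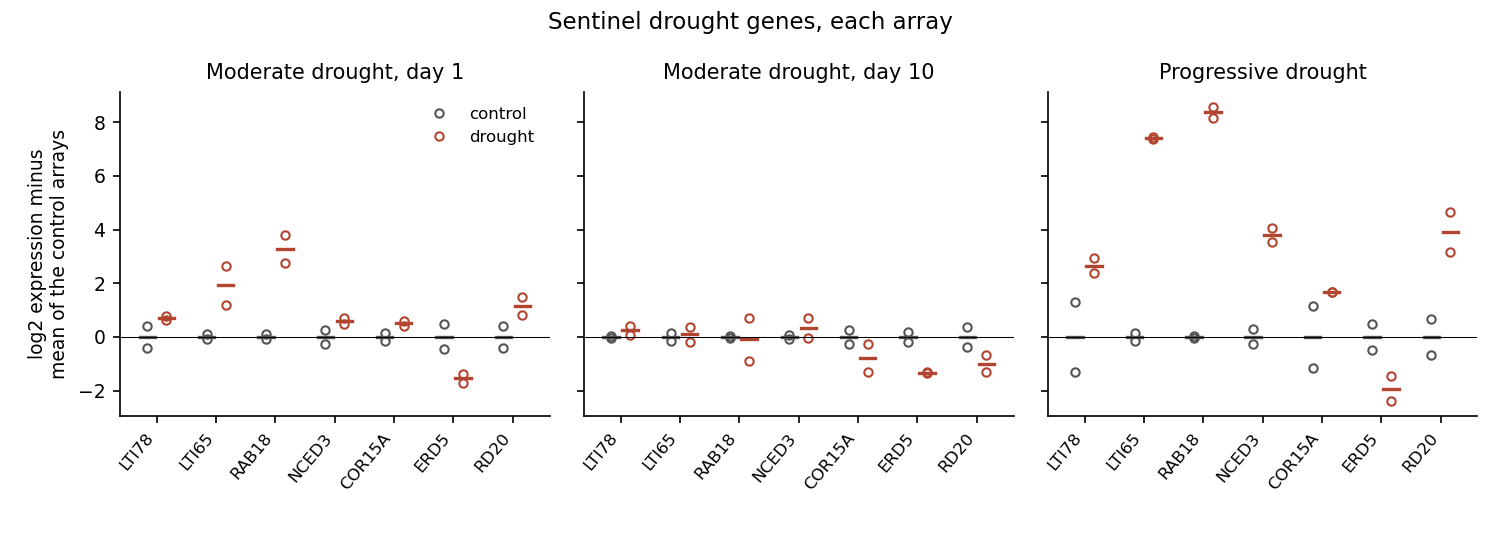
Log2 expression of the measured sentinel drought genes on each array relative to the mean of its own controls, for the 3 comparisons. Points are arrays and bars are means; RAB18 differed from its controls by 3.27 on day 1, −0.10 on day 10 and 8.37 in progressive drought.

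Lists of osmolyte, senescence, heat shock and flavonoid genes rose beside them. Synthesis genes of proline, galactinol and raffinose had a median of 1.84, with 7 of 12 rising and 1 falling by either adjustment (adjusted p = 0.0162; adjusted p = 0.346 with an estimated correlation). The galactinol synthase GolS2 (3.85) rose, and DIN10, a raffinose synthase-like gene, fell by 3.70. Listed beside them, the sucrose synthase SUS3 (4.57) and the alkaline alpha-galactosidase-like SIP2 (3.48) rose, though neither makes proline, galactinol or raffinose. Leaf senescence and sugar-starvation genes had a median of 0.94, with 8 of 18 rising and 2 falling, and 9 and 2 adjusted over the list alone (adjusted p = 0.00182; adjusted p = 0.483 with an estimated correlation). SAG21 (6.03), SAG29 (4.68), the senescence regulator NAC6 (4.02) and ACD1 (2.85), which opens the chlorophyll ring during its breakdown, rose, and DIN10 and DIN4 (−0.56) fell. Heat shock proteins and factors rose with a median of 0.71, 8 of 18 called and 10 adjusted over the list alone (adjusted p = 0.00182; adjusted p = 0.540 with an estimated correlation). HSP70 rose by 5.35 ± 0.65, and MBF1C (3.18), HSA32 (2.89) and HSFB2A (1.70) rose too. Flavonoid and anthocyanin synthesis genes rose with a median of 0.86, 3 of 17 rising and 1 falling by either adjustment (adjusted p = 0.043; adjusted p = 0.778 with an estimated correlation). The anthocyanin regulator PAP1 (MYB75; 3.08), F3H (2.70) and GSTF12 (2.14), which carries anthocyanin to the vacuole, rose, and the flavonol glycosyltransferase UGT78D1 fell by 0.92.

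All 3 lists of photosynthesis genes fell in progressive drought. Light-harvesting and photosystem genes fell with a median of −0.80, 35 of 37 called over all genes and 36 adjusted over the list alone (adjusted p = 4.2e-18; adjusted p = 0.211 with an estimated correlation). The plastocyanins PETE1 (−2.00) and DRT112 (−1.44), PSBQA (−1.89), a subunit of the oxygen-evolving complex, and the antenna gene LHCB6 (−1.32) were examples. With cyclic loess, which removes differences that follow intensity, the median was −0.14 and the adjusted p 0.0113. Chlorophyll synthesis genes fell with a median of −1.53, 15 of 16 called and all 16 adjusted over the list alone (adjusted p = 2.0e-11; adjusted p = 0.269 with an estimated correlation). CHLI2 (−3.34), GSA2 (−3.20), CHLI1 (−2.42) and POR C (−1.64) fell. Calvin cycle enzymes fell with a median of −1.18 and 15 of 17 called by either adjustment (adjusted p = 9.6e-09; adjusted p = 0.297 with an estimated correlation). GAPA-2 (−1.97) and HCEF1 (−1.76), the chloroplast fructose bisphosphatase, were among them, and cyclic loess gave a median of −0.66 (adjusted p = 5.3e-04).

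Lists of division and cell wall genes fell too. Cell division genes had a median of −0.97, with 20 of 26 falling over all genes and 21 adjusted over the list alone (adjusted p = 9.2e-11; adjusted p = 0.275 with an estimated correlation). The replication helicase genes PRL (MCM7; −2.09) and MCM4 (−1.15), PCNA1 (−1.99) and the cyclin CYCD3;3 (−1.39) were among them. Cellulose and pectin genes of the primary wall fell with a median of −0.58, 8 of 14 called and 11 adjusted over the list alone (adjusted p = 7.1e-05; adjusted p = 0.297 with an estimated correlation). The pectin methylesterase PME3 (−3.57), the cellulose synthase CESA5 (−1.08), COB (−0.93) and CSI1 (−0.81) were among them. The XTHs fell as a list, with a median of −0.18, a mean of −0.94, 8 of 26 falling and 1 rising by either adjustment (adjusted p = 0.0201; adjusted p = 0.480 with an estimated correlation). XTH4 (−3.45), XTH8 (−2.15) and XTH16 (−2.12) fell and XTH28 rose (0.74). Expansins, which loosen the wall for growth, fell with a median of −0.52, 8 of 25 falling and 1 rising, and 9 and 1 adjusted over the list alone (adjusted p = 0.0338; adjusted p = 0.574 with an estimated correlation). EXPA8 (−3.21), EXPA6 (−3.02), EXPB3 (−1.55) and EXPA5 (−1.10) fell and EXLB1 rose (4.96). Glucosinolate synthesis genes fell with a median of −0.93 and 6 of 21 called by either adjustment (adjusted p = 0.00974; adjusted p = 0.732 with an estimated correlation). IMS2 (MAM3; −1.74), SOT18 (−1.15) and the regulators MYB29 (−0.99) and MYB28 (−0.96) fell.

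Jasmonate response genes did not pass in progressive drought (adjusted p = 0.185; median 0.93), although CORI3 (2.72), JAZ12 (1.05) and COI1 (0.89) rose, and jasmonate synthesis was at an adjusted p of 0.866. Salicylate and defence genes were at 0.321, with PR5 at −2.47 among 3 members that fell. Vascular markers, with a median of 0.42, were at an adjusted p of 0.0666 and 2 members rose, while markers of guard cells (0.758), roots (0.721), the shoot apex (0.842) and the epidermis (0.947) did not pass. Across all 20 lists that did not pass, adjusted p ran from 0.0666 to 0.947.

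The equal-spread test may overstate the progressive counts. Simulations with the measured spreads gave 304.2 false calls each, where array weights gave 8.7. These simulations scaled every probe set by its group's root mean square SD and changed far fewer probe sets than were called here. The size of any excess among the measured calls is therefore not known. Of the 80 called genes that the naming rule took in progressive drought 1, GSTF12, lost its call with array weights. When 1 array was left out, 5 (ERD5, EXPA5, GSTF12, HSA32 and LTI78) lost their call. With the 4 arrays alone 22 of the 80 lost it, among them LTI78 (adjusted p = 0.218), ERD5 (0.115), RD20 (0.0680) and EXO (0.0755), as did 23 of the 38 members called outside the rule. Of the called members given outside the rule, ABA2 (adjusted p = 0.0997), ABA3 (0.0986), DIN4 (0.228), JAZ12 (0.0601) and COI1 (0.0911) did not pass with array weights, and these 5, NPQ1 and HB5 lost their call when 1 array was left out. Without drought replicate 2 the adjusted p became 0.15 for expansins and 0.102 for the XTHs, and without control replicate 1 it became 0.237 for anthocyanins and 0.495 for glucosinolates. Cyclic loess put anthocyanins at 0.0554, and control replicate 2 with drought replicate 1 alone put them at 0.51 and the XTHs at 0.204. Across the 12 fits without an array the median ran from 0.28 to 1.22 for heat shock, from 0.60 to 2.21 for senescence, from 0.38 to 1.03 for anthocyanins and from 0.99 to 2.12 for transcription factors. It ran from −1.24 to −0.11 for glucosinolates, from −0.60 to −0.22 for expansins and from −0.47 to −0.10 for the XTHs.

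The last question is whether the 3 drought effects differ or share genes. Between day 10 and day 1 limma called 0 probe sets, with 1472 at an unadjusted p under 0.05, while array weights called 7. Between lists, the effect on day 10 lay below that on day 1 for 10 lists and above it for 0. Jasmonate response genes were among the 10 (median difference −1.55, adjusted p = 7.5e-05; adjusted p = 0.506 with an estimated correlation), as were ABA- and dehydration-responsive genes (−0.55, adjusted p = 2.3e-04; adjusted p = 0.419 with an estimated correlation). Against day 1, the progressive effect was more positive for 1129 probe sets and more negative for 1559. LEA4-5 differed by 6.66 and the heavy-metal-associated protein gene HIPP22 by 5.54, against −4.68 for GER1. Against day 10, it was more positive for 1003 probe sets, led by LEA7 (9.80) and RAB18 (8.47), and more negative for 1634, led by GER1 (−4.66) and EXPA8 (−4.53). The light-harvesting list differed in both, with medians of −0.81 against day 1 (adjusted p = 1.8e-19) and −0.77 against day 10 (adjusted p = 8.5e-19), each at an adjusted p = 0.1003 with an estimated correlation. With cyclic loess the fall of this list in progressive drought was much smaller (camera adjusted p = 0.0113), and the differences were not tested with it. Without 1 of the 4 day 1 arrays the 2688 differences from day 1 became 1232 to 1778, and the 2637 from day 10 became 1680 or 1392 without control replicate 1 or 2 of day 10 and 3976 without progressive drought replicate 2.

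Probe sets called in moderate drought were compared with those called in progressive drought. All 3 that rose on day 1 rose in progressive drought, where 0.376 would be shared if calls were independent (Fisher's exact p = 0.00197), and CSD2, the 1 that fell, fell again. Of the 10 that rose on day 10, 7 rose in progressive drought and 1 fell (1.25 if independent; Fisher's exact p = 4.1e-05), and 10 of the 13 that fell on day 10 fell again (1.88 if independent; Fisher's exact p = 7.4e-07). The comparisons share 1 spread estimate per probe set and genes are not independent, so these p-values are too small by an unknown amount. In the separate fits on 4 arrays, progressive drought shared 37 of the 108 day 1 rises and 27 of the 79 falls. Day 10 had 0 calls in such a fit. Probe sets called on both day 1 and day 10 numbered 0 with all 12 arrays and 15 with array weights, which was chosen for the overlap after seeing the data. Effects correlated across probe sets (Pearson) at 0.51 between day 1 and progressive drought, 0.29 between day 10 and progressive drought, and 0.26 between day 1 and day 10, where probe sets are not independent replicates. On ranks (Spearman) these were 0.35, 0.34 and 0.22, so day 1 was hardly closer to progressive drought than day 10 was. Without control replicate 1 or 2 or drought replicate 1 of day 10 the 17 shared with progressive drought became 0, because no day 10 call was left, and the 4 shared by day 1 became 1 without either control array of day 1.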

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

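Of the tests weighed here, those of wounding and of every explanation for the progressive replicates were chosen only after the result was seen. The effect of progressive drought differed from that of moderate drought in a test of the difference itself. Against day 1 it was more positive for 1129 probe sets and more negative for 1559, and against day 10 for 1003 and 1634. The largest named differences from day 1 were 6.66 for LEA4-5, 5.54 for HIPP22, 5.51 for TSPO, 5.49 for LTI65 and 5.31 for HB-12 on the positive side. On the negative side they were −4.68 for GER1, −4.25 for GER3, −4.01 for GASA6, −3.92 for XTH6 and −3.83 for HBI1. From day 10, LEA7 differed by 9.80, RAB18 by 8.47, LEA4-5 by 7.74, LTP4 by 7.72 and LTI65 by 7.31, and GER1 by −4.66, EXPA8 by −4.53, CSD2 by −4.25, GASA6 by −4.25 and HBI1 by −4.16. These 20 differences kept their calls in every alternative that tested them, but their sizes are approximate where an array level was dim.

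Lists were set apart by the same test of a difference between effects. From day 1 to day 10, the median effect differed by −1.29 for the sentinel genes, −0.55 for ABA- and dehydration-responsive genes, −0.26 for osmolyte synthesis, −0.26 for LEA proteins and dehydrins, and −0.14 for XTHs. It differed by −0.82 for jasmonate synthesis, −1.55 for jasmonate response, −0.30 for aquaporins, −0.20 for wax and cutin genes and −0.43 for vascular markers. With an estimated correlation the adjusted p of these 10 lay between 0.208 and 0.686. Progressive drought differed from day 1 by a median of 2.76 for the sentinel genes, 1.68 for ABA- and dehydration-responsive genes, 2.76 for PP2C phosphatases, 1.22 for ABA 8'-hydroxylases, 1.59 for transcription factors, 1.26 for osmolyte synthesis and 1.56 for LEA proteins. Senescence genes differed by 1.04, heat shock genes by 0.64, wounding genes by 0.53 and wax genes by 0.29. The differences were −0.52 for expansins, −0.29 for XTHs, −0.58 for cellulose and pectin, −0.81 for light harvesting, −1.13 for the Calvin cycle, −1.48 for chlorophyll synthesis, −0.62 for cell division, −0.57 for aquaporins and −0.73 for glucosinolates. With an estimated correlation the adjusted p of these 20 lay between 0.1003 and 0.686.

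Progressive drought differed from day 10 by a median of 3.48 for the sentinel genes, 2.45 for ABA- and dehydration-responsive genes, 2.89 for PP2C phosphatases, 1.31 for ABA 8'-hydroxylases, 1.32 for transcription factors, 1.82 for osmolyte synthesis and 2.13 for LEA proteins. The median difference was 2.48 for jasmonate response, 0.72 for heat shock, 0.37 for wax, 1.31 for senescence, 0.71 for wounding and 0.38 for vascular markers. It was −0.38 for cellulose and pectin, −0.77 for light harvesting, −1.14 for the Calvin cycle, −1.46 for chlorophyll synthesis and −0.67 for cell division. With an estimated correlation the adjusted p of these 18 lay between 0.1003 and 0.637. None of the list differences was tested with cyclic loess, which shrank the progressive falls of light harvesting and the Calvin cycle. Control probe sets, which the comparisons leave out, also held a signal above the control arrays: in progressive drought the 25S rRNA set was higher by 1.24, with a gap of 0.61 between the groups, and the 5S rRNA set by 1.31, with a gap of 0.56. The 25S rRNA set was lower by 0.44 on day 1 and by 0.68 on day 10, with both drought arrays below both control arrays, and the 5S rRNA set differed by −0.21 and 1.19.

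Jasmonate response genes were lower on day 10 of moderate drought, with a mean of −1.65. From the clock index difference and the slope within the progressive groups, a difference in harvest time between drought and control plants would account for 8.75% of that change. The standard error of 12.2 covers only the index difference. The slope (−0.49) comes from 1 replicate difference in each progressive group, and its error is not included. Harvest time is therefore left open. One deviating array is argued against by the highest adjusted p of 8.3e-04 over the 4 fits that leave out a day 10 array. The wounding and touch list fell too, with a mean of −0.49, short of the jasmonate change. Its standard error of 0.23 is taken over list members, as if the genes were independent. How strongly each list responds to handling was not measured. Wounding or handling of the control plants is therefore left open, as a part or as the whole cause. Variation between pools is left open as well. Replicate 1 minus 2, the list mean differed by 2.90 in the progressive controls, −1.60 in progressive drought and 1.03 in day 1 drought. The difference was smaller in the day 1 controls (0.0065), the day 10 controls (−0.54) and day 10 drought (−0.51). An effect of the drought itself remains a candidate explanation that these data leave untested, and the list's adjusted p was 0.54 with an estimated correlation.

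Replicate arrays of the 2 progressive groups differed in opposite directions, with a correlation of −0.49 across probe sets between the control and the drought difference. A difference in harvest time is a candidate explanation: the clock index differed between replicates by −3.54 in the controls and by 5.00 in drought, and the smaller of these, 3.54, exceeds the largest in the other groups, 0.80. A difference in drought severity between the control pools gave a correlation of 0.0902 with the drought effect. The replicates also differed in clock genes, so this low value does not exclude it. LTI78 (11.71 and 9.07), COR15A (12.42 and 10.12) and RD20 (8.34 and 7.02) were higher in control replicate 1 than 2. ERD5, which fell in drought, was lower (6.41 and 7.38). NCED3 and RAB18 differed less, and LTI65 went against the drought effect (4.48 and 4.78), so severity is left open. Spike-in differences were −0.24 in the controls and −0.49 in drought, with the same sign. Quantile normalisation had already evened out array brightness, so the spike-ins cannot decide on it. A difference in severity between the drought pools gave a correlation of 0.24 with the drought effect, and it cannot be told apart because both pools were wilting and the labels give no measure of severity per pool. Harvest times per array were not among the labels used here, so the first explanation may be checked only against such a record.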

How the results depend on the processing

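The crossed replicate pairing and the fits on single progressive arrays, and for overlaps and lists the array weights and the fits on 4 arrays, were chosen only after the result was seen; where no cause is given, the cause was not tested. Day 1 calls (4) became 28 with an intensity trend, 165 with array weights, 187 with its 4 arrays alone, 1 with the replicate block within each comparison and 2 at adjusted p under 0.01. Leaving out 1 array gave 1 to 31. Day 10 calls (23) became 158 with array weights, 13 with the replicate block over all 12 arrays, 0 with the block within each comparison, 15 with cyclic loess, 0 with its 4 arrays alone (3038 at an unadjusted p under 0.05 in limma) and 5 at adjusted p under 0.01. Leaving out 1 array gave 0 to 92. Progressive calls (5797) became 1575 with the 4 arrays alone, 3746 at adjusted p under 0.01 and 2674 with a change of at least 1 log2 unit as well; leaving out 1 array gave 4648 to 6354, and array weights gave 4275. The stricter thresholds lower counts by construction. Fits on 4 arrays or without 1 array have fewer arrays to estimate the spread, which does not account for counts that went up. With 2 arrays per group, leaving out 1 takes its whole group out of the spread estimate. Day 1 and day 10 counts went up without a progressive array, and the progressive groups had the widest replicate spread (root mean square SD 0.31 and 0.37).

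Differences between day 10 and day 1 (0, with 1472 at an unadjusted p under 0.05 in limma) became 7 with array weights, 1 with the replicate block over all arrays and 0 to 1 leaving out an array. Differences of progressive drought from day 1 (2688) became 1365 with the block within comparisons, 1142 at adjusted p under 0.01, 1740 with a change of at least 1, 4114 with crossed pairing and 4624 with progressive control replicate 2 and drought replicate 1 alone. Leaving out 1 array gave 1232 to 3974. Differences from day 10 (2637) became 1435, 1201, 4207 and 4851 with the block within comparisons, the 0.01 threshold, crossed pairing and those single arrays, and 1392 to 3976 leaving out an array. Calls shared by day 1 and day 10 (0) became 1 with cyclic loess, 15 with array weights and 0 to 6 leaving out an array. Calls shared by day 1 and progressive drought (4) became 2 at adjusted p under 0.01, 64 with 4 arrays, 106 with array weights and 1 to 24 leaving out an array. Calls shared by day 10 and progressive drought (17) became 4 at adjusted p under 0.01, 9 with the block over all arrays, 0 with 4 arrays, 92 with array weights and 0 to 67 leaving out an array. List shifts (38) became 0 with an estimated correlation and 21 with fry, and stayed between 27 and 45 in the other settings; cyclic loess ended 5 of the 38 and array weights 1. Of the 38, fry kept 16 and lost 22: all 10 of day 1 (adjusted p = 0.0603 to 0.210), 9 of 10 on day 10 (0.175 to 0.701, jasmonate response at 0.392) and 3 of 18 in progressive drought (expansins, anthocyanins and glucosinolates, 0.0805 to 0.236). Fry also called 5 progressive lists outside the 38. Signs turned for 3 sentinel genes on day 10, none of them called. LTI65 was at −0.04 without control day 10 replicate 2, −0.18 without drought day 10 replicate 1 and 0.38 without drought day 10 replicate 2. RAB18 was at −0.91 and 0.71, and NCED3 at −0.050 and 0.70, without drought day 10 replicate 1 and 2. Of the genes taken by the naming rule, 3 of 4 called on day 1, 17 of 17 on day 10 and 5 of 80 in progressive drought lost their call in at least 1 fit without an array, and 22 of the 80 with the 4 arrays alone. Lists that did not pass without control day 10 replicate 2 were the phosphatases (adjusted p = 0.0501), cellulose and pectin (0.0827), wounding (0.103), defence (0.0827) and glucosinolates (0.285) on day 10. The sentinel genes on day 1 were at 0.0604 without control day 1 replicate 1, and the shoot apex markers missed the threshold in 6 of 12 such fits. In progressive drought, the XTHs were at 0.0786 without control replicate 1, anthocyanins at 0.191 without drought replicate 2 and glucosinolates at 0.103 without drought replicate 1. No scaling moved the median of all probe sets by over 0.1 log2 units. The alternative for several probe sets per gene was not run, as there was 1 probe set per locus. That for cross-hybridising probe sets was not run either. Names made from locus codes do not mark shared probes, so cross-hybridisation between close relatives, such as LTP3 and LTP4, is left open. Signal over background limits the lists too. The filter on dim probe sets ended 13 shifts. On day 1 these were cell division (adjusted p = 0.221), vascular markers (0.122) and the shoot apex (0.806), and on day 10 cellulose and pectin (0.0834), defence (0.122), cell division (0.0516) and wounding (0.233). In progressive drought they were ABA 8'-hydroxylases (0.205), osmolyte synthesis (0.0814), expansins (0.0639), anthocyanins (0.122), glucosinolates (0.0516) and senescence (0.142).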

Other observations

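The test of 1 deviating array for the copper genes was chosen only after the result was seen, as were the genes named below outside the naming rule. Other lists did not pass with camera in progressive drought, and their called members are counted here. Of the aquaporins, which carry water across membranes, 7 fell and 1 rose (adjusted p = 0.0988; median −0.35). TIP2 (−2.77), DELTA-TIP (−2.65) and PIP1C (−1.92) fell, and PIP2;5 rose (0.80). Wax and cutin genes had 8 rises and 3 falls (adjusted p = 0.118). Besides LTP3 and LTP4, KCS2 (2.93), WSD1 (2.58), which makes wax esters, and KCS6 (1.67) rose. Among ethylene genes 2 rose and 4 fell (adjusted p = 0.866). The ethylene-forming oxidase gene EFE (−2.53) fell while ACS2 (2.15), which makes the substrate of that step, rose. Antioxidant enzymes had 2 rises and 7 falls (adjusted p = 0.321; down with fry, 0.0190). CSD2, CSD1 (−2.61) and the thylakoid ascorbate peroxidase TAPX (−1.32) fell, and GPX2 (1.31) rose.

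Hormone, starch and clock lists did not pass with camera in progressive drought either. Aux/IAA genes had 3 rises and 8 falls (adjusted p = 0.234; down with fry, 0.00902), with AXR3 at −1.53. Brassinosteroid genes had 1 rise and 4 falls (adjusted p = 0.126; down with fry, 0.0190), with the synthesis gene DWF1 at −1.44. Gibberellin genes had 2 rises and 2 falls (adjusted p = 0.934), and GA2OX6, which inactivates gibberellin, was at 2.77. In starch breakdown 3 genes rose and 2 fell (adjusted p = 0.836), with the beta-amylase BAM1 at 3.31 and the alpha-amylase AMY3 at −1.68. Of the clock genes 1 rose, ZTL (0.80; adjusted p = 0.341 for the list), and it did not pass with array weights (adjusted p = 0.0624). Among wounding and touch genes 4 rose and 1 fell (adjusted p = 0.1304), with the zinc finger gene STZ at 3.57. Leaving out 1 array ended the calls of PIP1C (highest adjusted p = 0.143), ZTL (0.138), GPX2 (0.0998), PIP2;5 (0.0931), AMY3 (0.0910), AXR3 (0.0909) and WSD1 (0.0636). The actin control probe set at the 3' end differed by −1.20 on day 1 and by −1.54 in progressive drought, and both drought arrays lay below both control arrays in each, which chance gives in either direction for 33.3% of probe sets. On day 10 that probe set differed by 0.51, and both drought arrays lay above both control arrays. The actin probe set at the 5' end differed by 0.35 on day 1, 0.27 on day 10 and −0.09 in progressive drought, with overlapping arrays in each.

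On day 1 the copper/zinc superoxide dismutase genes CSD2 (−3.41) and CSD1 (−2.06) and their chaperone CCS (−2.07) were low while the iron enzyme gene FSD1 was at 1.48. Of the 4, only CSD2 was called with all 12 arrays. The drought and control arrays of these genes were at least 1.14 log2 units apart and by at least 2.17 times the larger replicate difference. With 1 deviating array, the other array of its group would lie with the opposite group. The gaps therefore argue against a single deviating array for these 4 genes. They add no support for the calls, as 3 of the genes were named for an adjusted p under 0.05 on these same arrays. FSD1 was picked after its values were seen. On the separate progressive arrays CSD2 (−5.47), CSD1 (−2.61) and CCS (−2.82) fell and were called, while FSD1 (0.56) was not called. A copper deficiency type response is a candidate explanation that remains open: of 16 other copper genes listed before that test 14 were measured and 10 moved in the listed direction, with a mean of 0.22 in that direction (exact sign-flip permutation test, two-sided, p = 0.184). YSL2 is among the 14 and was also 1 of the 4 probe sets called on day 1, so the set is not fully separate from those calls. CCH (1.22), YSL2 (1.20) and COPT2 (0.88) moved that way, and the laccase genes LAC17 (0.85) and LAC4 (0.60) moved the other way, although LAC4 is the vascular marker IRX12 and vascular markers rose that day.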
